A study of Staphylococcus aureus with 4 samples.

How the data were processed

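RNA was sequenced from Staphylococcus aureus ATCC-29213 without treatment and after 12 h with the decoction at 1, 2 and 4 mg/ml, with 1 library each. The labels do not give the culture time of the untreated sample. Per the file headers, the authors deposited counts of reads assigned uniquely to each gene, and these counts add up to the total printed in each header. The deposited RPKM values equal the reads divided by gene length and by that total, scaled to the usual RPKM unit, for every gene listed. The aligner, the counter and the filters are not given in the sources used here. Genes with no read in a library are left out of its list and were taken as 0. The deposited gene annotation, a KEGG orthology entry and a best protein database match per gene, is text from the authors, and its unit is other than a measurement. That table also holds 21 columns of per-sample values for 7 libraries whose names do not match the labels, and none of them was used.

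Gene identifiers are locus tags. All 2436 matched the reference table for assembly ASM1342v1. It was used only for names, gene order and a check of gene lengths, since no assembly version is named with the deposited values. Gene lengths were taken as coding lengths. All reference lengths are multiples of 3, and the deposited length equals the reference length for 2417 of the 2418 genes with reads. The reference gave 219 symbols and the deposited annotation another 408. A name taken from the annotation is the authors' best match, and genes with near-identical copies, such as leukocidin subunits, may share or lose reads. Whether counting used strand is not given in the sources used here, so overlapping genes are uncertain too. The cells are of another strain than the reference, so genes that differ in sequence could lose reads.

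Log2 fold changes were computed from RPKM with a pseudocount of 1, over genes with RPKM of at least 10 in at least 1 of the libraries compared, and genes at or above 2-fold were counted. With 1 library per dose no p-value was computed for a dose against untreated. Ratios of reads per library total carry exact 95% conditional binomial intervals. The dose trend was tested on the counts with edgeR 4.0.16 (quasi-likelihood, TMM factors), with limma 3.58.1 on log2(RPKM + 1) and DESeq2 1.42.0 as alternatives, in R 4.3.3. Adjusted p-values use Benjamini-Hochberg with a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

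The themes and symbols of 35 gene lists were fixed before the data were examined, as were the comparisons, the tests and most alternatives. Because few genes had symbols, patterns on product text were added after the annotation had been read and before any expression comparison. After first values had been seen, 1 gene with a ribosomal S1 domain was taken out of the ribosomal list, an exclusion decided from its annotation. A list's median was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries only, and lists with fewer than 3 measured members were not summarised. Random lists drew genes singly, while neighbouring genes of a list can vary together. Percentiles of lists made up of neighbours are therefore more extreme than independent genes would give. For the 25 genes that went in opposite directions at 1 and 2 mg/ml, counting intervals that excluded a ratio of 1 were not used as a test of depth, since genes chosen for 2-fold differences have such intervals by selection. Reads were instead assigned to 2 parts at random, 20 times, and genes chosen in 1 part were tested in the other.

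Genes were named by a rule. It takes, for each dose, the 10 highest and 10 lowest log2 fold changes among genes with a symbol and at least 100 reads over both libraries, up to 4 members of each list with the largest difference at 4 mg/ml, and agrA, hla, spa, sarA, saeR, norA, mepA, icaA and icaB. The alternatives were pseudocounts of 0.1 and 5, no expression filter, RPKM of at least 50, median-centred libraries, TPM, TMM factors, leaving out the most abundant genes, thresholds of 1.5-fold and 4-fold, other dose codings and leaving out each library.

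The steps were tested on simulated data. For 4 mg/ml against untreated, over 1828 genes with counting noise only, 99 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3.0 were recovered, and 94.7% of intervals held the true ratio. For the dose trend, over 1893 genes with a dispersion of 0.1, 57 of 100 genes with a slope of 0.5 on the log2 scale per mg/ml and 100 of 100 with a slope of 1 were called, with 7 unchanged genes called. With a dispersion of 0.01, 99 of 100 and 100 of 100 were called, with 15 unchanged genes called. The simulated trends were straight lines, and both dispersions were set rather than estimated from these libraries. The shares therefore do not tell how many such genes would be called in the real data.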

Results

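The data set holds RNA sequencing of Staphylococcus aureus strain ATCC-29213, a methicillin-susceptible laboratory reference strain, grown without or with a decoction of Radix Paeoniae Rubra, the dried root of red peony used in traditional Chinese medicine. The decoction was present for 12 h at 1, 2 or 4 mg/ml. Each dose and the untreated culture is represented by 1 library, so no difference between libraries has a replicate check. Every comparison with untreated cells uses the same untreated library. A difference seen at more than 1 dose is therefore not an independent repeat and could come from that library. Reads assigned to genes totalled about 14718000 in the untreated library, 15358000 at 1 mg/ml, 18024000 at 2 mg/ml and 18223000 at 4 mg/ml. The median gene with reads had 431.5, 613.5, 543.5 and 837.5 reads in that order. Intervals given for fold differences are exact 95% conditional binomial intervals of the ratio of reads per library total. They cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The title of the series names gene transcription and drug resistance as its subjects. Log2 fold changes are on the log2(RPKM + 1) scale, which understates the change of weakly expressed genes. Members of a gene list are counted where RPKM reached 10 in either library, so a weakly expressed gene can enter through a higher value in the treated library.

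The first comparison asked how the transcriptome at 1 mg/ml differed from that of untreated cells. Genes of nitrate reduction, which lets the cell respire without oxygen, and of nitrite reduction were lower. The nitrate reductase subunit genes narH and narG were 25.1-fold (24.4 to 25.8) and 20.6-fold (20.3 to 21.0) lower, narJ had a log2 fold change of -3.96, and the nitrite reductase gene nirB was 15.7-fold (15.2 to 16.3) lower. The anaerobic metabolism list had 1 of 28 measured members at least 2-fold higher and 18 at least 2-fold lower. Pyrimidine synthesis had 6 of 10 members lower and 1 higher, with carA, which starts the pathway, 7.75-fold (7.14 to 8.41) lower. Purine synthesis had 9 of 16 members lower and none higher, and purL had a log2 fold change of -2.27. Among 56 ribosomal protein genes 28 were lower and 2 higher, and rplN was 5.95-fold (5.82 to 6.09) lower. On the other side stood genes for sugar uptake and use, with 27 of 48 members higher and 2 lower. The gluconate permease gene gntP was 15.4-fold (15 to 15.9) higher, the mannitol transporter gene mtlA 7.28-fold (6.74 to 7.88) higher, and ulaA, annotated as an ascorbate transporter subunit, 24.4-fold (23.4 to 25.5) higher. In the oxidative stress list 15 of 19 members were higher and none lower. The largest differences in that list at 4 mg/ml included SAOUHSC_02949, annotated as a glutathione peroxidase, whose log2 fold change was 2.58 at 1 mg/ml.

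At 1 mg/ml, 610 of 1838 genes differed at least 2-fold, 502 higher and 108 lower. The median log2 fold change of all compared genes was 0.55, and with the libraries centred on that median 193 genes were higher and 217 lower. After centring oxidative stress had 7 members at least 2-fold higher and 1 lower, sugar uptake 20 higher and 4 lower, and ribosomal proteins 35 lower and none higher. Anaerobic metabolism then had 20 lower, purine synthesis 12 and pyrimidine synthesis 7, with none higher in each. The list medians of anaerobic metabolism (-2.09), pyrimidine synthesis (-2.15), purine synthesis (-1.30), ribosomal proteins (-1.01) and other amino acid synthesis (-0.40) each lay at percentile 0.0 of 10000 random lists matched on mean expression. The drug target median of -0.13 lay at percentile 2.1. The tRNA synthetase median of 0.05, at percentile 0.7, became -0.51 after centring. Medians of oxidative stress (1.39) and sugar uptake (1.20) lay at percentile 100, and that of branched-chain amino acid synthesis (1.24) at 98.9. Without the expression filter the branched-chain list had a median of 0.91 at percentile 95.8, inside the central 95%.

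The second comparison set 2 mg/ml against untreated cells. Glycolytic genes were higher, with 9 of 13 members at least 2-fold higher and none lower. The genes pgk, tpiA and gpmI, which act in the lower part of glycolysis, were 18.9-fold (18.5 to 19.3), 17.7-fold (17.4 to 18.1) and 15.5-fold (15.3 to 15.6) higher, and gapA had a log2 fold change of 3.54. The fermentation gene adhE, an acetaldehyde and alcohol dehydrogenase, was 53-fold (51.8 to 54.2) higher. A pair of neighbouring genes annotated as sucrose-specific phosphotransferase transporters, SAOUHSC_02661 and SAOUHSC_02662, were 212-fold (192 to 235) and 183-fold higher. The gluconate permease gene gntP had a log2 fold change of -0.14. In the arginine deiminase list, a route that yields ATP from arginine, 4 of 6 members were higher and none lower, with arcA 15-fold (13.1 to 17.3) higher. The citric acid cycle list had 7 of 14 members lower and none higher, and acnA had a log2 fold change of -1.88. Nitrate reductase genes were lower than in the same untreated library, narG by 9.02-fold (8.92 to 9.12) and narH by 8.0-fold (7.87 to 8.12). Among histidine synthesis genes hisG was 24.9-fold (14.0 to 48.9) lower, and hisZ was 249-fold (68.5 to 2065) lower on 2 reads against 407.

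Between 2 mg/ml and untreated cells 452 of 1761 genes differed at least 2-fold, 247 higher and 205 lower. The median of all compared genes was 0.07, and centring gave 213 higher and 235 lower. Purine synthesis (-1.53) and ribosomal proteins (-0.65) lay at percentile 0.0, branched-chain amino acid synthesis (-1.0) at 0.1, the citric acid cycle (-0.96) at 0.2, secreted toxins (-1.05) at 0.3, other amino acid synthesis (-0.53) at 0.4, clotting and immune evasion (-0.89) at 1.6 and drug targets (-0.58) at 2.0. For clotting and immune evasion only 4 of 12 members were measured, 1 of them at least 2-fold higher and 2 lower. Arginine deiminase (2.77), glycolysis (1.87) and sugar uptake (0.96) lay at percentile 100, and oxidative stress (0.82) and iron acquisition (0.77) at 99.8. Anaerobic metabolism, with 6 members higher and 13 lower, had a median of -0.31 at percentile 4.8, inside the central 95%, and 2.5 among unmatched random lists. Without the expression filter secreted toxins had a median of -0.32 at percentile 11.1, and among unmatched random lists clotting and immune evasion lay at percentile 2.6.

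The third comparison set 4 mg/ml against untreated cells. The same sucrose-annotated transporter gene and its partial neighbour were 378-fold (342 to 418) and 238-fold (195 to 294) higher. The glycerol-3-phosphate dehydrogenase gene glpD was 29.2-fold (28.3 to 30.2) higher, gntP 29.0-fold (28.1 to 29.9) higher and lacB, of the lactose and galactose pathway, 22.2-fold (16.2 to 31.2) higher. The sugar uptake list had 28 of 49 members higher and 4 lower. The gene glmS, which makes the amino sugar precursor of peptidoglycan, was 16.2-fold (15.8 to 16.7) higher, alsS, an acetolactate synthase, 16.8-fold (15.3 to 18.4) higher, and arcA 20.1-fold (17.6 to 23.1) higher. All 7 urease genes were at least 2-fold higher, ureA by 27.5-fold on 3 reads in the untreated library, with an interval of 9.14 to 135. Of 40 iron acquisition genes 20 reached an RPKM of 10 in either library, 17 of them higher and none lower, and without the filter the list median was 1.14 at percentile 100. Counted among the higher ones was fur, annotated as a transcriptional regulator rather than an uptake gene, at 3.67-fold (3.39 to 3.98). Heat shock had 9 of 14 members higher and none lower, with log2 fold changes of 2.10 for both ctsR and mcsB. In the metal homeostasis list 12 of 17 members were higher and 2 lower, and the lower ones included SAOUHSC_02389, annotated as a cation efflux protein, at 11.4-fold (9.69 to 13.6). Nitrate reductase genes were lower, narH by 19.7-fold (19.2 to 20.2), as were purine synthesis genes, with 10 of 16 members lower and none higher. The iron storage gene ftnA had a log2 fold change of -2.49.

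At this dose 743 of 1828 genes differed at least 2-fold, 608 higher and 135 lower. The median of all compared genes was 0.61, and centring gave 268 higher and 302 lower. After centring iron acquisition had 9 members at least 2-fold higher and heat shock 4, with none lower in either. Metal homeostasis then had 7 higher and 2 lower, sugar uptake 24 higher and 8 lower, and purine synthesis 13 lower and none higher, while all 7 urease genes were at least 2-fold higher. Purine synthesis (-1.80), ribosomal proteins (-0.52) and anaerobic metabolism (-0.48, with 7 members higher and 14 lower) lay at percentile 0.0, secreted toxins (-0.93) at 0.1, clotting and immune evasion (-1.04) at 0.2, branched-chain amino acid synthesis (-0.48) at 0.4, surface adhesins (-0.41) at 1.3 and drug targets (-0.23) at 2.0. For clotting and immune evasion only 4 of 12 members were measured, 1 of them at least 2-fold higher and 2 lower. The regulator median of 0.19 lay at percentile 0.8 and was -0.42 after centring. Arginine deiminase (3.10), urease (2.70), glycolysis (1.86), iron acquisition (1.58) and sugar uptake (1.5) lay at percentile 100, and metal homeostasis (1.45), heat shock (1.36) and oxidative stress (1.27) at 99.9. All 7 urease genes, and the 4 higher arginine deiminase genes, each lay in a single run of neighbouring genes. Those 2 percentiles thus overstate how many separate genes they rest on. Without the expression filter secreted toxins had a median of -0.12 at percentile 3.7.

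**Figure D1:**
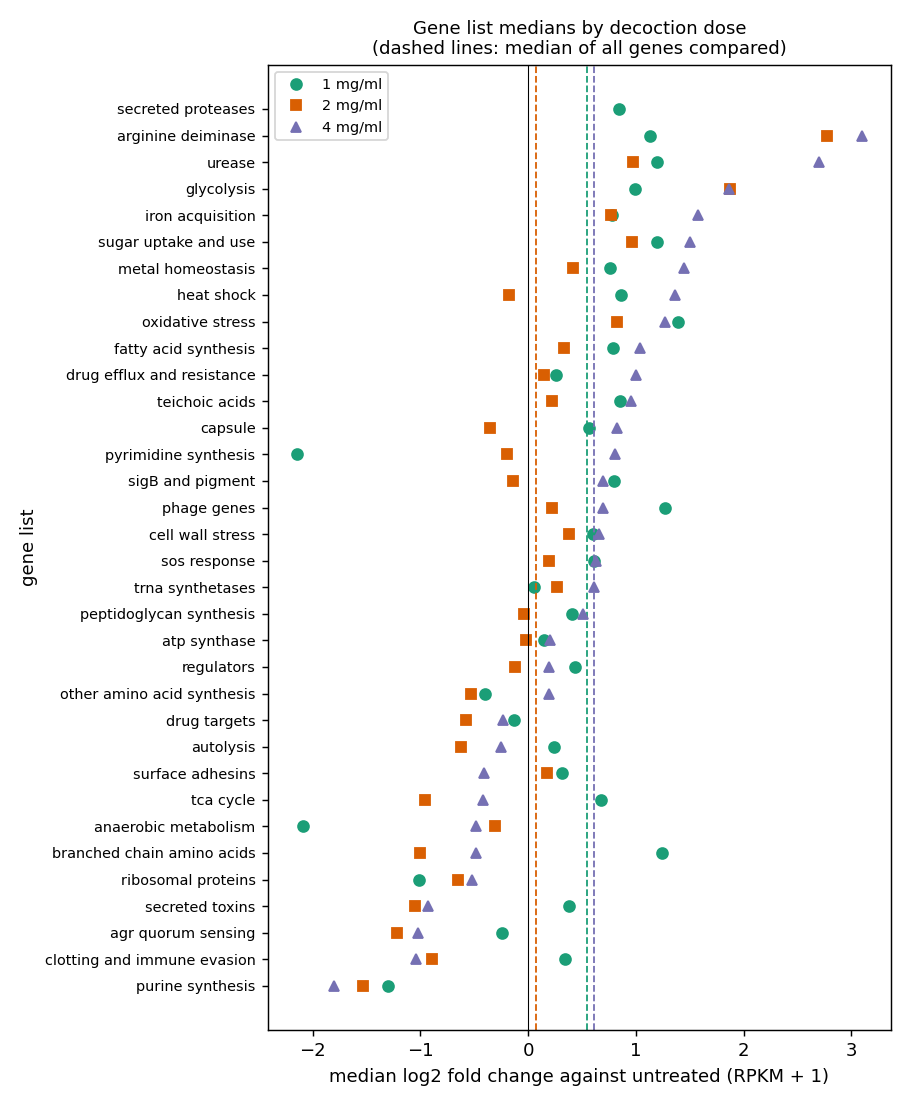
Median log2 fold change of each gene list against untreated (horizontal axis, RPKM + 1) at 1, 2 and 4 mg/ml, with 1 library per dose. Dashed lines mark the median of all compared genes, 0.55, 0.07 and 0.61. The point farthest to the right is the arginine deiminase median at 4 mg/ml, 3.10.

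Lists inside the central 95% of random lists at 4 mg/ml had medians of 0.20 for ATP synthase, 0.82 for capsule synthesis, 0.66 for cell wall stress, 1.04 for fatty acid synthesis, 0.51 for peptidoglycan synthesis, 0.69 for phage genes, 0.69 for the sigma B operon and pigment, 0.63 for the SOS response, 0.95 for teichoic acids, 0.61 for tRNA synthetases and 0.81 for pyrimidine synthesis. The medians were -1.02 for the agr quorum-sensing list, -0.25 for autolysis, -0.42 for the citric acid cycle and 0.19 for other amino acid synthesis. After centring, ATP synthase was at -0.41, peptidoglycan synthesis at -0.1 and other amino acid synthesis at -0.42. The tRNA synthetase median equalled the median of all compared genes, 0.61. The other positive medians given here stayed positive. Among unmatched random lists agr quorum sensing, autolysis and the citric acid cycle lay outside the central 95%, at percentiles 1.5, 1.9 and 0.1, and without the expression filter agr quorum sensing and the citric acid cycle did, at 1.5 and 2.0. At 1 mg/ml the 3 measured secreted protease genes had a median of 0.84 at percentile 51.0. The ica biofilm list had too few measured members to summarise.

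Drug resistance, named in the series title, was examined with a list of efflux and resistance genes and a list of drug targets. At 4 mg/ml 11 of the 22 efflux and resistance genes measured, from a list of 33, were at least 2-fold higher and none lower. After centring 3 were higher and 2 lower. The list median of 1.00 lay at percentile 93.4, inside the central 95% of matched random lists, and without the expression filter the median of 0.94 lay at 97.9, outside it. Among the higher genes were SAOUHSC_00246, annotated as a drug transporter, at 5.27-fold (3.94 to 7.18) higher, and mepR, a regulator of the efflux pump gene mepA, at 3.29-fold (2.62 to 4.17) higher. SAOUHSC_01448, annotated as the quinolone resistance protein NorB, was 7.48-fold (6.29 to 8.95) lower at 1 mg/ml, 6.75-fold (6.33 to 7.20) higher at 2 mg/ml and 2.99-fold (2.79 to 3.20) higher at 4 mg/ml. This swing was not particular to a resistance gene. Nearby SAOUHSC_01450, annotated as an amino acid permease, had log2 fold changes of -3.63 and 2.43 at 1 and 2 mg/ml. SAOUHSC_01451, a threonine dehydratase, had -1.95 and 1.11, and SAOUHSC_01452, an alanine dehydrogenase, -3.45 and 1.4. Another listed gene annotated as NorB, SAOUHSC_00058, was not among the named genes. The efflux pump gene norA was lower at each dose, by 1.28-fold, 2.00-fold and 1.30-fold. The pump gene mepA was higher, by 1.5-fold (1.02 to 2.22), 1.51-fold (1.04 to 2.21) and 1.81-fold (1.27 to 2.62). It was near the floor, with 46 reads in the untreated library. At 4 mg/ml its log2 fold change was 0.65, beside a median of 0.61 for all compared genes. The pseudocount shrinks the change of so weak a gene, so these values do not compare directly. SAOUHSC_00246 was also near the floor without treatment, with 53 reads. At 1 and 2 mg/ml the list medians were 0.26 and 0.15, at percentiles 5.2 and 67.5. After centring they were -0.29 and 0.07, so the sign at 1 mg/ml turned. Of 13 drug target genes at 4 mg/ml 2 were higher and 4 lower, or 2 and 5 after centring. The drug target list shares rplC and rplD with the ribosomal protein list, and rplD had a log2 fold change of -1.32. The drug target result is therefore partly the same as the ribosomal one. The trimethoprim target gene folA was 4.44-fold (4.12 to 4.80) higher and the triclosan target gene fabI 4.01-fold (3.81 to 4.22) higher, while rpoB, the rifampicin target gene, had a log2 fold change of -1.29.

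Among virulence genes, hla, agrA, sarA, spa, saeR, icaA and icaB were fixed in advance, while the delta-hemolysin gene hld is given for its values and as a member of fixed lists. It was 1.90-fold (1.79 to 2.01), 7.78-fold (7.09 to 8.56) and 9.79-fold (8.84 to 10.9) lower at 1, 2 and 4 mg/ml. The alpha-hemolysin gene hla was 2.00-fold, 2.37-fold and 5.30-fold lower at the 3 doses. The quorum-sensing response regulator gene agrA had log2 fold changes of -0.12, -1.09 and -0.83, and the global regulator gene sarA 0.42, -1.90 and -1.35. The protein A gene spa had 1.08, 0.24 and -0.75, and saeR had 0.66, -0.56 and 0.39. Centred on the median of all genes, 0.42 for sarA and 0.39 for saeR fall below 0. The biofilm genes icaA and icaB had 14 and 4 reads in the untreated library. At 1 mg/ml icaA was 2.19-fold (1.14 to 4.44) higher on 32 reads. Its log2 fold change there was 0.6, beside a median of 0.55 for all compared genes. The pseudocount shrinks the change of so weak a gene, so these values do not compare directly. The intervals of icaA at 2 and 4 mg/ml, and those of icaB at the 3 doses, included no difference.

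**Figure D2:**
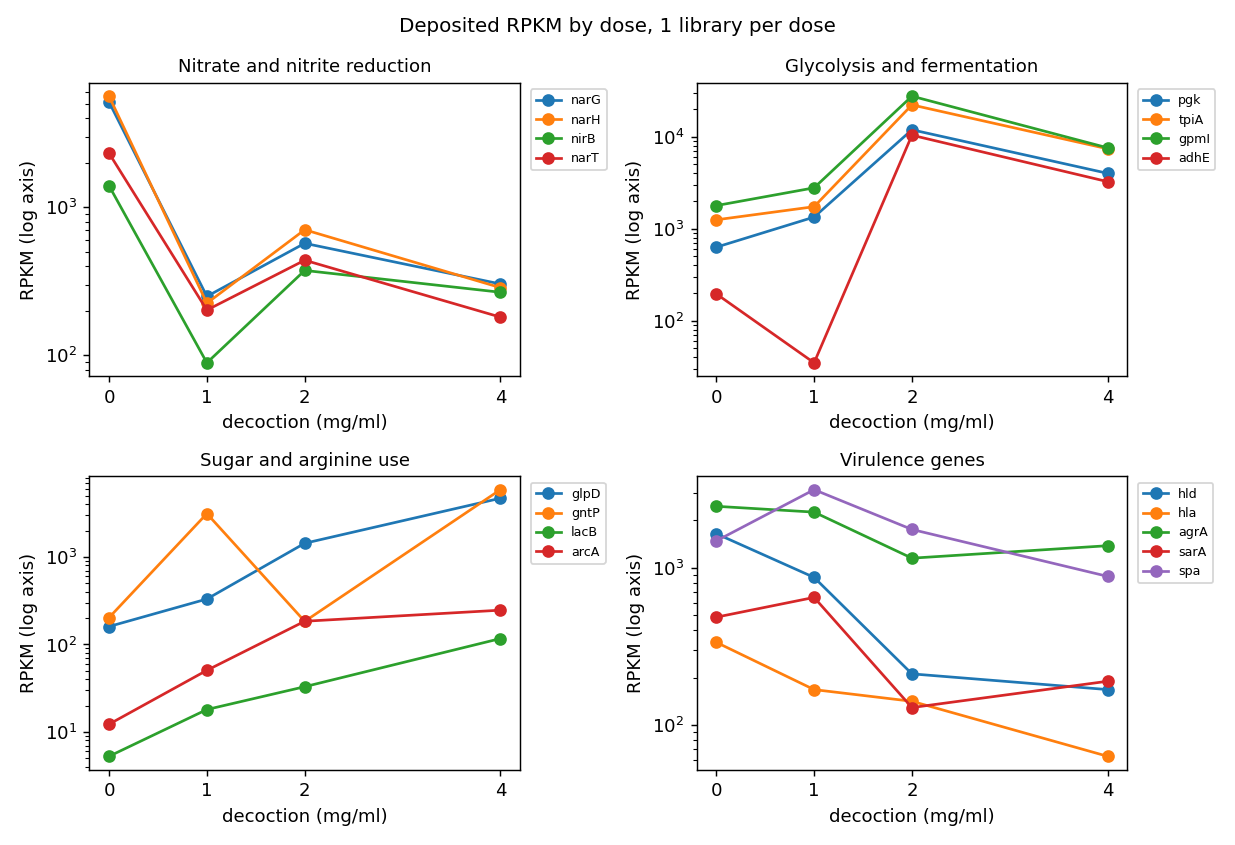
Deposited RPKM (log axis) against decoction dose in mg/ml for named genes, each point being 1 library. RPKM of narG goes from 5146 in the untreated library to 249.8 at 1 mg/ml, and that of adhE from 34.9 at 1 mg/ml to 10397 at 2 mg/ml.

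Successive doses were compared to see whether differences grew with dose. Between 1 and 2 mg/ml 547 genes differed at least 2-fold, 106 higher and 441 lower, and between 2 and 4 mg/ml 375 differed, 340 higher and 35 lower. With centring the splits were 213 higher and 185 lower, and 103 higher and 99 lower. Of 1893 genes, 225 rose in RPKM at every step and 46 fell at every step. With centred libraries the counts were 158 and 140. Random ordering of each gene on its own would give 78.9 each way. Genes share the same libraries and do not vary independently, so a count above that figure is no test of dose. Across genes, which are not independent replicates, the 2 and 4 mg/ml libraries had a Pearson r of log2 RPKM of 0.963, and every other pair of libraries 0.92 or lower.

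A linear trend in dose was the test the design allowed. It treats departures from a straight line as error, and 2 residual degrees of freedom remained. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 1893 genes at 0.05, and 279 had an unadjusted p under 0.05. The smallest adjusted p among named genes was 0.073, for lacB, lacD, SAOUHSC_02389 and SAOUHSC_02467, the last annotated as an acetolactate decarboxylase. limma on log2 RPKM also called 0, with 209 at an unadjusted p under 0.05. DESeq2 called 84 genes, 42 in each direction. Without the untreated library edgeR called 0 genes, without the 1 mg/ml library 72, without the 2 mg/ml library 21 and without the 4 mg/ml library 5.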

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

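The values below were picked out because they went in opposite directions at different doses. The differences between doses were not tested, and the depth test given here was chosen after the result was seen. The branched-chain amino acid synthesis list had a median log2 fold change of 1.24 at 1 mg/ml, -1.0 at 2 mg/ml and -0.48 at 4 mg/ml. The fermentation gene adhE had -2.46 at 1 mg/ml and 5.72 at 2 mg/ml. SAOUHSC_01448, annotated as NorB, had -2.74 and 2.73, and the isocitrate dehydrogenase gene icd had 1.98 and -1.01. Nearby SAOUHSC_01450, SAOUHSC_01451 and SAOUHSC_01452 went in the same directions as SAOUHSC_01448. In all, 25 genes were at least 2-fold higher at 1 of these doses and at least 2-fold lower at the other. With centred libraries the count was 20, of which 15 were among the 25. For the genes as counted without centring, low depth is argued against. When the reads of each library were split at random into 2 equal parts and such genes were chosen in 1 part, at least 84.6% of them kept both directions in the other part, with counting intervals that excluded a ratio of 1 at both doses, in each of 20 splits. The split covers counting error only. A dose effect and a difference between single cultures, such as their growth stage at harvest, stay open, because each dose has 1 library.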

How the results depend on the processing

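The alternative that uses library totals without TMM factors was chosen after seeing the data. Counts of 2-fold differences against untreated stayed within 1.5 times under every alternative except the thresholds. At 1.5-fold they were 1060, 845 and 1176 genes at 1, 2 and 4 mg/ml, and at 4-fold 118, 88 and 193. For 2 against 1 mg/ml the thresholds gave 991 and 108 genes, and for 4 against 2 mg/ml 877 and 33. The 4 against 2 mg/ml count of 375 became 202 with centring, 206 with TMM factors and 246 without the most abundant genes. The cause was not tested beyond the rescaling itself. With TMM factors 49.1%, 43.1% and 46.6% of the 2-fold different genes were higher at 1, 2 and 4 mg/ml. Genes ordered with dose numbered 154 up and 145 down with TMM factors. For efflux and resistance genes at 4 mg/ml the count of 2-fold differences went from 11, all higher, to 5 with centring. Of these 5, 3 were higher and 2 lower. The dose trend called 0 genes under the other edgeR and limma settings, 84 with DESeq2, and between 0 and 72 when each library was left out. The cause was not tested. Of 100 list medians, 2 that lay outside the central 95% changed sign with centring, the tRNA synthetases at 1 mg/ml (-0.51) and the regulators at 4 mg/ml (-0.42). Another 12, inside the central 95%, also changed sign, among them efflux and resistance genes at 1 mg/ml (-0.29). Without a filter 3 list medians came inside the central 95%, secreted toxins at 2 and 4 mg/ml (-0.32 and -0.12) and branched-chain amino acid synthesis at 1 mg/ml (0.91), and with unmatched random lists 1 did, clotting and immune evasion at 2 mg/ml. In the other direction 7 list medians came outside without a filter and 6 with unmatched lists, among them phage genes at 1 mg/ml and the agr list at 2 and 4 mg/ml under both. Depth limits genes such as icaB, with 4 reads untreated. No paired analysis was possible because each group has 1 library.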

Other observations

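Runs of at least 4 neighbouring genes that all differed at least 4-fold in the same direction at 4 mg/ml were listed after the data had been seen. The longest held 9 genes, from SAOUHSC_02448 to lacR, with a median log2 fold change of 3.53, and the next 8 genes, from SAOUHSC_02557 to ureD, with 2.70. A run of 4 genes annotated for riboflavin synthesis, starting at ribH, had medians of -0.42 and -0.49 at 1 and 2 mg/ml and 2.35 at 4 mg/ml. The 4 genes starting at ulaA, annotated as a phosphotransferase system and its regulator, had 5.04, 3.81 and 3.52 at the 3 doses. A run from SAOUHSC_00291 to SAOUHSC_00294, annotated with a carbohydrate kinase, a pseudouridine phosphate glycosidase and transporters, was lower throughout, at -2.45, -2.27 and -2.76.

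The most abundant transcripts differed between libraries. The pyruvate formate lyase gene pflB took 11.02% of reads in the untreated library (named after its value was seen), and the 10 most abundant genes took 36.21%, 23.38%, 32.44% and 22.88% at 0, 1, 2 and 4 mg/ml. The test of whether this accounts for the excess of higher genes was chosen after that excess was seen. Leaving out the 18 genes that ranked among the 10 most abundant in any library, the share of 2-fold different genes that were higher went from 82.3% to 66.5% at 1 mg/ml and from 81.8% to 71.0% at 4 mg/ml. Both stayed above 60%, a bound that was also set after the excess was seen. This argues against those 18 genes as the whole cause, while the drop leaves them open as a part of it. Other abundant genes were left in, so the test does not cover them. With TMM factors no excess of higher genes remained. Their log2 shifts of -0.55 at 1 mg/ml and -0.63 at 4 mg/ml nearly cancelled the medians of 0.55 and 0.61. Centring removes the excess by construction and TMM factors largely do so too, so neither decides anything.

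Ribosomal protein genes are short, so gene length bias between libraries may lower them together. Among random lists matched on both coding length and mean expression, the list's median at 1 mg/ml lay at percentile 0.0, which argues against length as the cause. This test was set before its result was seen. A slower growth of the culture remains a hypothesis that was not tested.

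For the dose trend, the test over orders was chosen after the counts had been seen. All 24 orders of the 4 libraries called at least as many genes as the real order, which called 0, and the highest of the others called 1. With 0 genes called in the real order this outcome was fixed, and it says nothing about chance.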
